A study of Caenorhabditis elegans with 2 samples.

How the data were processed

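Transcription factor ChIP-seq was done on whole late embryos of a Caenorhabditis elegans strain that expresses PHA-2 with a C-terminal GFP-FLAG tag, with an antibody against GFP, in 2 biological replicates of 1 group. Chromatin was fragmented by sonication, per the labels. Both replicates were called against the same control, per the text deposited with each library. The control library was not analysed here.

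The values used are those of the deposited peak lists in narrowPeak format on the ce11 and ce10 assemblies: for each assembly 1 relaxed list per replicate, 1 relaxed list of the pooled replicates and 1 optimal list kept by the authors' IDR procedure, 4 lists per assembly. Each peak has a signal value from the authors' peak caller, a −log10 q-value as deposited, and a summit offset. Per the labels, the assemblies are ce11 and ce10. The aligner, the peak caller and its settings are not given in the sources used here. Checked on the files, the optimal list consists of the 878 highest-signal peaks of the pooled ce11 list (and the 897 highest on ce10), so IDR acted as a signal threshold on the pooled list. Most pooled peaks share a single width (99.6% of the ce11 list, with a median of 456 bp). Signal values were used to rank, describe and match peaks, to compare median signal between classes of peaks within a list, and to correlate the replicate lists across peaks. They were not averaged across replicates, because each list was called separately. No list gives read counts, so the depth of each replicate is unknown, and all intervals given are for the counted peaks or genes and not for sequencing.

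Positions were compared with the WBcel235 genome, the same assembly as ce11. All ce11 peaks lie inside the lengths of its chromosomes. Gene positions, biotypes and symbols are from Ensembl release 115 (46926 genes, of which 19985 are protein-coding). Of its 634 tRNA genes, 632 carry no symbol there, and 605 were given the RefSeq name with the same WormBase gene identifier, which also gave the amino acid. No coordinate was moved between assemblies, and ce10 lists were used only against each other and for counts by chromosome.

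A gene was called bound when an optimal summit lay from 1000 bp upstream to 500 bp downstream of its 5′ end. Location classes were assigned in the order promoter window, 5′ UTR, 3′ UTR, coding exon, non-coding exon, intron, intergenic. Shares of summits were tested by 1000 circular shifts of the summits along each chromosome (two-sided). Gene lists were tested by Fisher's exact test (two-sided, 25 lists, Benjamini-Hochberg adjustment). Their background was all other protein-coding genes, or all other genes of any biotype for the tRNA, the snRNA and snoRNA, and the microRNA lists. The 13 fixed motifs and all 2080 6-base words were tested by McNemar's exact test. It compared the 151 bp window at the summit with 1 flank window 500 bp away on a seeded side. The share of peaks on X was tested by an exact binomial test, medians and correlations by 100000 permutations, and the neighbourhood of pha-2 by 10000 random gene starts. Where 0 members were bound, the limit given is 3 counts over the number of members. The tissue lists are background lists fixed from textbook knowledge. They cover regulators of the pharynx, pharyngeal muscle, pharyngeal gland and cuticle, body wall muscle, intestine, epidermis, neurons, and germline and oocyte.

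The lists, motifs, tests and rule for named genes were fixed before the data were examined. The rule takes the 25 optimal peaks of highest signal, every bound gene of the pharynx regulator, pharyngeal muscle and Hox lists, up to 6 bound genes of highest signal from each other list that passes its test, and pha-2, ceh-22, pha-4, tbx-2, myo-2 and unc-119 whether bound or not. For tRNA and for snRNA and snoRNA genes, the 6 were taken from the nuclear genes, a departure from the rule made after the values were seen, because the tRNA genes of highest signal are mitochondrial and stand with the peaks. Bound genes of lists that did not pass and the further nuclear peaks were named after their values were seen. The microRNA pattern matched 8 genes, since most microRNA genes are named with the prefix cel in this annotation, so all 261 microRNA genes were also counted by biotype.

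Alternatives set beforehand were other promoter windows (500 bp upstream only, and 2000 bp upstream to 500 bp downstream), the nearest gene end, other rules for overlap, lists of 500 and 5000 peaks, the 439 optimal peaks of highest signal, the 878 strongest peaks of each replicate in place of the optimal list, ce10, other motif windows and flanks, and shuffled sequence. Chosen after seeing the data were the settings without mitochondrial peaks, without peaks within 200 bp of tRNA or snoRNA genes, with only genes that have a relaxed pooled summit as background, with protein-coding gene ends for X, and with only summits outside the promoter window for location classes.

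The steps were first tested on simulated data with known answers. In 20 runs of 878 random summits, the promoter share was called in 0, and it was called when 20% of summits were moved to gene ends. In 20 runs with 1 of 25 lists changed, that list was called in 20, and unchanged lists were called 3 times over all runs. A word planted in simulated windows came 1st among 2080 words, and 0 of 12 motifs not planted were called. In these runs genes were bound independently and summits were placed at random. They therefore do not cover genes that share a peak or a difference in base composition between summits and flanks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.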

Results

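The series holds ChIP-seq of PHA-2, the Hex-type homeobox factor of Caenorhabditis elegans that is needed to form the isthmus of the pharynx. The protein carried a C-terminal GFP-FLAG tag from a transgene (strain OP687, an unc-119 mutant background in which the transgene array is wgIs687), and chromatin from whole late embryos of both sexes, 3 h after synchronisation by egg bleaching, was precipitated with an antibody against GFP. There was 1 group with 2 biological replicates and no second condition, so the questions are where the tagged factor was found on the genome, at which genes, and whether the replicates gave the same places. The peak lists were deposited on the ce11 and ce10 assemblies. Unless stated otherwise, positions and counts are for ce11, and the signal value of a peak is the authors' own. The optimal list, which is the set the authors kept by their irreproducible discovery rate (IDR) procedure, held 878 peaks. The relaxed lists behind it held 23371 peaks in replicate 1, 24336 in replicate 2 and 30000 in the pooled replicates. The number of reads behind each list is unknown, so no interval from sequencing depth can be given.

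Most of the strongest PHA-2 peaks overlapped between the replicates. Of the 878 optimal peaks, 721 (82.1%) held the summit of 1 of the 878 strongest peaks of replicate 1, and 683 (77.8%) of replicate 2. Both replicates were met in 556 peaks (63.3%), 1 of them only in 292 and neither in 30. When the 878 strongest peaks of each replicate were set against each other, 64.1% of those of replicate 1 held a replicate 2 summit, against a median of 2.16% in 1000 circular shifts of the summits along their chromosomes (two-sided permutation p by these shifts = 0.002, the smallest they can give). Across the 873 optimal peaks present in both relaxed lists, signal values correlated with Spearman's rho = 0.629 and, on the log10 scale, Pearson's r = 0.843 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give; 2 correlations were computed). Without the 2 peaks farthest from the median of replicate 1, r was 0.834. Over the 852 nuclear peaks, a setting chosen after the data were seen, rho was 0.601 and r 0.754. These correlations run across peaks, which are not independent replicates, and over peaks that were chosen by their signal in the same 2 libraries. Some optimal peaks were also matched to the same replicate peaks, so the 873 pairs are not all distinct. The effect of these repeats on the correlations was not tested. Both replicates were called against the same control, which the circular shifts do not account for, so the shifts do not tell how much of the overlap comes from the control. The overlap depended on the length of the list, with 72.8% for the 500 strongest peaks and 44.2% for the 5000 strongest.

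**Figure D1:**
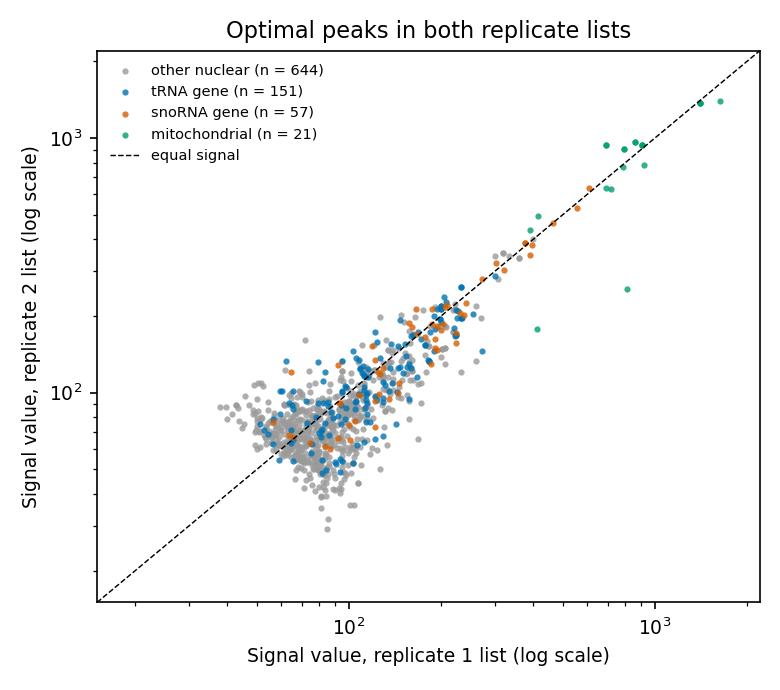
Signal value of each optimal peak in the replicate 1 list (x axis) and the replicate 2 list (y axis), both on log scales, coloured by what lies within 200 bp of the summit (nuclear tRNA gene, snoRNA gene, other nuclear position) or by being on the mitochondrial chromosome. The 873 peaks found in both lists follow the line of equal signal, with a median ratio of replicate 1 to replicate 2 of 1.10.

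The highest signals lay on the mitochondrial chromosome. It held 22 of the 878 optimal peaks, all 10 of the highest ones and 16 of the 25 highest, with a median signal of 1188 against 158 for the 856 nuclear peaks. The highest peak of all spanned 10566 to 11055 of the mitochondrial chromosome, downstream of the 5′ end of a mitochondrial rRNA gene (WBGene00014472, summit at +468), with a signal of 3008 in the pooled list, 1633 in replicate 1 and 1396 in replicate 2. The second spanned 8910 to 9930 and had its summit 202 bp upstream of a mitochondrial tRNA gene (WBGene00014467), with a signal of 2776 and the tRNA genes WBGene00014468, WBGene00014469 and WBGene00014470 also in reach. Other peaks among the 25 highest lay in the windows of ND1 (1610) and ND6 (949) and at COX3 (1437 and 676), which encode subunits of respiratory complexes. The next intervals, with signals of 1849 and 1750, had summits in the windows of the tRNA gene WBGene00014473 and of the protein-coding gene WBGene00010964. Several mitochondrial peaks shared an interval and differed in their summit, so that the 22 peaks covered 15 intervals. In each replicate alone, mitochondrial peaks were again the 10 highest.

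The 9 nuclear peaks among the 25 highest were led by genes of small structural RNAs. The strongest lay 51 bp upstream of the snoRNA gene Y43F8C.22 (WBGene00045120) on chromosome V, at 19643016 to 19643442, with a signal of 1237 (609 in replicate 1 and 633 in replicate 2). It was followed by peaks at the snoRNA gene W03C9.9 (chromosome II, 11960630 to 11961025, signal 1089), at the neighbouring snoRNA genes C51F7.4 and C51F7.3 (chromosome V, 12303458 to 12303829, signal 927, summit inside C51F7.4), and at the snoRNA genes ZK265.10 (776), F55A11.10 (752) and T06C12.16 (738). The other 3 lay upstream of the protein-coding gene K12H4.5 (summit at −529, signal 803), at the 5′ end of the microRNA gene cel-mir-52 (690; chromosome IV, 14033819 to 14034279), and 58 bp upstream of atx-2 (680), the ataxin-2 gene, which encodes an RNA-binding protein.

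Because so many of these places were mitochondrial, the next 16 nuclear peaks were also listed, a choice made after the values were seen. They included the snoRNA genes ZK994.7 (625), T03F7.8 (623), T02E1.9 (547) and H09I01.2 (470), the tRNA genes C04A11.t1 (a tRNA-Leu gene, 592), F41D9.t3 (tRNA-Asn, 487), W03G11.t1 (tRNA-Lys, 444) and F57F5.t1 (tRNA-Ile, 438), and rpr-1 (445), the RNA component of RNase P. Also among them was the divergent start of ears-2, which encodes a glutamyl-tRNA synthetase, and uncp-18 (586). Of the 25 highest nuclear peaks, 11 had a snoRNA gene as the gene with the closest 5′ end, 4 a tRNA gene and 3 a protein-coding gene.

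Summits were concentrated at gene starts. Of the 878 summits, 706 (80.4%) fell in the window from 1000 bp upstream to 500 bp downstream of an annotated 5′ end, against a median of 40.7% in circular shifts (95% range 37.5 to 43.6; two-sided permutation p = 0.002). Counting the starts of protein-coding genes only, the share was 49.5% against 27.4% in the shifts (permutation p = 0.002). The shares of the classes sum to 100%, so those of the other classes fall together as that of promoter windows rises: 0.683% in coding exons (shift median 15.4%), 9.45% in introns (24.3%) and 8.31% between genes (15.6%), each with an adjusted permutation p of 0.0028 from the circular shifts over 7 classes. The 6 classes past the threshold also included 3′ UTRs (0.569% against 2.16%) and non-coding exons (0.342% against 1.14%, adjusted permutation p = 0.035), and 5′ UTRs did not pass it (0.228% against 0.456%, adjusted permutation p = 0.328). Among the 172 summits outside promoter windows, set against shifts of those summits that also landed outside, a comparison added after the data were seen, 2 of 6 classes passed the threshold. Coding exons were still low, 3.49% against 26.0%, while intergenic summits were above the shifts, 42.4% against 26.7% (adjusted permutation p = 0.012 each). Introns did not differ (48.3% against 40.6%, adjusted permutation p = 0.3). The lower intron and intergenic shares among all summits therefore do not show avoidance of these classes. The share in non-coding exons became 12.3% when the promoter window was set to 500 bp upstream and 0 bp downstream. Peaks in promoter windows had a higher median signal than the other peaks, 165 against 144 (difference 20.9, n = 706 and 172 peaks, permutation p = 0.00035). The difference was 11.2 with that smaller window. In the replicate lists, whose signal values are lower than the pooled ones, it was 18.4 in replicate 1 (94.2 against 75.8) and 10.5 in replicate 2 (84.0 against 73.5).

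**Figure D2:**
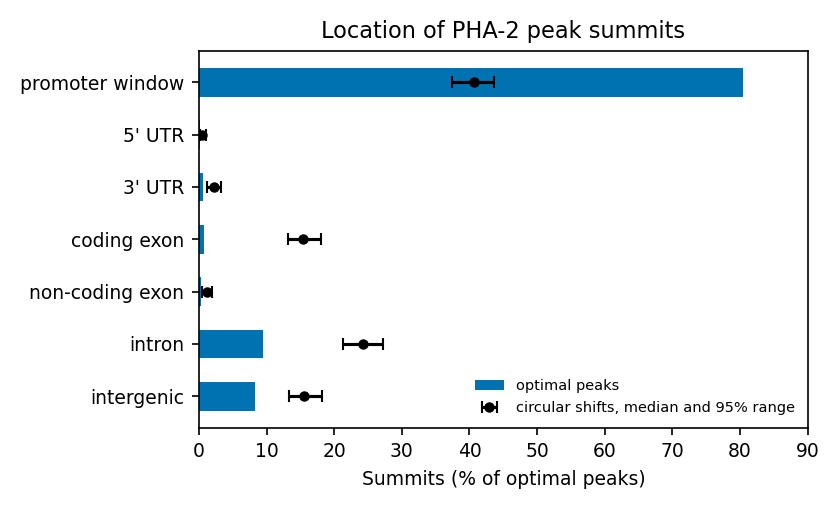
Share of the 878 optimal peak summits in each location class (bars, x axis in % of peaks), with the median and 95% range of 1000 circular shifts (points and whiskers). The promoter window holds 80.4% of summits, above the shift range of 37.5 to 43.6.

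Genes of tRNA, snRNA and snoRNA were bound more often than other genes, and tRNA genes had the highest bound share of the 25 fixed gene lists in the chosen window. Of 634 tRNA genes, 193 (30.4%, 95% Clopper-Pearson interval 26.9 to 34.2) held a summit in their promoter window, against 2.43% of all other genes (odds ratio 17.6, 95% interval 14.7 to 21.1; adjusted p = 4.6e-142, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 25 lists). Of the 475 snRNA and snoRNA genes, 87 (18.3%) were bound, against 2.65% of other genes (odds ratio 8.25, 6.49 to 10.5; adjusted p = 1.93e-43, Fisher's exact test). Circular shifts gave a median of 29 bound tRNA genes and 6 bound snRNA and snoRNA genes (adjusted permutation p = 0.0125 for each). With the window of 500 bp upstream only, 57 tRNA genes were bound (8.99%, odds ratio 7.75, adjusted p = 3.66e-28, Fisher's exact test), fewer than the 12.8% of snRNA and snoRNA genes and the 22.1% of ribosomal protein genes in that window. By the nearest 5′ end, 125 tRNA genes were bound (19.7%). Mitochondrial genes contributed 22 of the tRNA genes, and 171 of the 612 nuclear ones were bound. The peaks behind these lists were also stronger: 171 peaks in tRNA windows, mitochondrial ones included, had a median signal of 215 against 157 for the other promoter peaks (difference 57.9, permutation adjusted p = 3.5e-05), and 86 peaks in snRNA and snoRNA windows had 242 against 161 (difference 81.3, permutation adjusted p = 3.5e-05). Without the mitochondrial peaks, a setting chosen after the data were seen, 155 peaks in tRNA windows had 203 against 155 (difference 47.9). The 6 bound nuclear tRNA genes of highest signal were C04A11.t1, F41D9.t3, W03G11.t1 and F57F5.t1, given above, together with ZK994.t2 (tRNA-Lys), whose window shares the peak of ZK994.7, and C42D8.t1 (tRNA-Ile, signal 450). Neighbouring genes share a peak in these counts, so they are not independent of each other. The other genes set against the tRNA list and the snRNA and snoRNA list include 15363 nuclear piRNA genes, of which 0.475% were bound. These lower the share of other genes and so raise both odds ratios.

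Ribosomal protein genes were the most often bound protein-coding list in the chosen window. A summit lay in the promoter window of 19 of 77 (24.7%, 15.6 to 35.8), against 2.72% of other protein-coding genes (odds ratio 11.7, 6.94 to 19.8; adjusted p = 2.2e-12, Fisher's exact test). Of these, 9 encode proteins of the large subunit and 10 of the small subunit. The strongest was at rpl-3 (WBGene00004414, chromosome III, peak 3867479 to 3867676, summit at −244 from the 5′ end) with a signal of 376 (184 in replicate 1 and 183 in replicate 2). It was followed by rpl-15 (331), rps-28 (260), rpl-20 (252), rps-20 (228) and rps-26 (209), and all 19 summits lay upstream of the annotated 5′ end, at a median distance of 306 bp (recorded as −306). By the nearest 5′ end, 11 of 77 were bound (14.3% against 3.92%, odds ratio 4.09, adjusted p = 0.00134, Fisher's exact test). In that setting they stood 10.4 points above other genes, and translation initiation and elongation factors 11.4 points. For ribosomal protein genes, the 439 optimal peaks of highest signal gave 14.3% against 1.36%, with an odds ratio of 12.1 (6.33 to 23.2). Translation initiation and elongation factors were also bound more often than other genes, 6 of 39 (15.4%, 5.86 to 30.5) against 2.78% (odds ratio 6.36, 2.66 to 15.3; adjusted p = 0.00438, Fisher's exact test). The 6 were eif-3.C (signal 253) and eif-3.E (126), subunits of initiation factor eIF3, eef-1A.1 (120) and eef-1A.2 (153), which encode elongation factor eEF1A, iff-2 (154), an eIF5A gene, and eif-2Bgamma (120). In the 439 optimal peaks of highest signal the difference from other genes was 1.16 percentage points (adjusted p = 1, Fisher's exact test). With only genes that have a relaxed pooled summit as background, the difference was 12.3 points, against 12.6 with all genes, and did not pass (adjusted p = 0.093, Fisher's exact test). The replicates placed the eif-3.E peak far apart, at rank 482 and rank 11993. The peaks of eef-1A.1 and eif-2Bgamma were the weakest of the optimal list, at ranks 877 and 878.

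**Figure D3:**
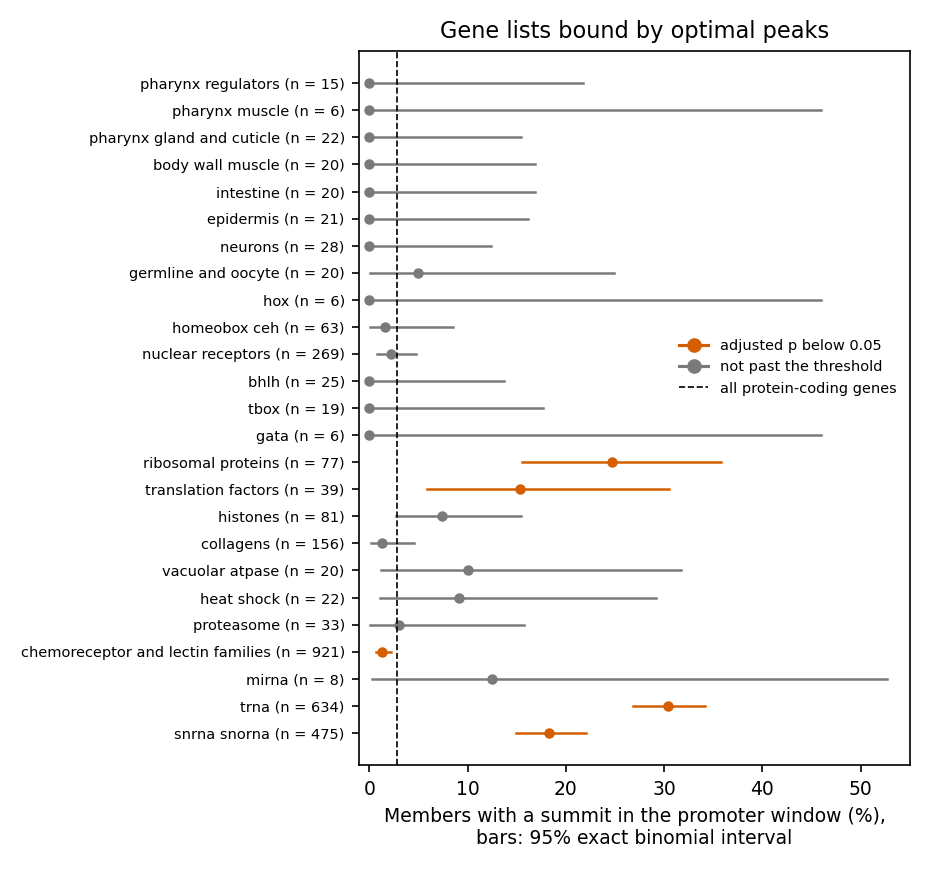
Share of the members of each fixed gene list with an optimal summit in the promoter window (points, x axis in %), with 95% exact binomial intervals. The 5 coloured lists passed the test after adjustment; the dashed line marks all protein-coding genes (2.80%).

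Other lists of broadly used genes did not pass. Histone genes were bound in 6 of 81 cases (7.41%; his-67 and his-68 share a peak, as do his-31 and his-32, and the others are hil-7 and his-37; adjusted p = 0.109, Fisher's exact test). This list passed in the top peaks of replicate 2 alone (adjusted p = 0.00409, Fisher's exact test) and with a window of 2000 bp upstream (adjusted p = 0.0407). The heat shock list had 2 of 22 members bound, hsp-60 (286) and hsp-1 (274), which encode a mitochondrial chaperonin and a constitutive HSP70. Of the vacuolar ATPase subunits, 2 of 20 were bound (vha-12 and vha-15), of the proteasome subunits 1 of 33 (rpn-7), and of the collagens 2 of 156 (col-85 and col-185). Both collagen summits lay within 200 bp of a tRNA gene. The large families of F-box, MATH, lectin and chemoreceptor genes were bound less often than other genes, 12 of 921 (1.30% against 2.87%, odds ratio 0.446, 0.251 to 0.793; adjusted p = 0.0143, Fisher's exact test), led by math-33 (291), clec-53 (262), sri-5 (245), srh-269 (208), clec-126 (197) and srh-16 (191). Of these, the summits of srh-269 and clec-126 lay within 200 bp of a tRNA gene. Circular shifts, which keep the clustering of these families, gave a median of 10 bound members, so the lower share did not hold against them (adjusted permutation p = 1). It was also not past the threshold in the top peaks of replicate 2 alone (adjusted p = 0.0876, Fisher's exact test) or in the 439 optimal peaks of highest signal (adjusted p = 0.22). Of the microRNA list, 1 of the 8 genes that its naming pattern matched was bound, mir-1831, which the annotation classes as an snRNA gene (adjusted p = 0.565, Fisher's exact test).

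None of the fixed genes of the pharynx had an optimal summit in its promoter window. The 15 regulators of pharynx fate (among them the FoxA gene pha-4, the NK-2 gene ceh-22 and the T-box gene tbx-2), the 6 contractile genes of pharyngeal muscle and the 22 gland and cuticle genes gave 0 of 43. This allows a bound share of up to 6.98% by 3 counts over the number of members (upper 95% Clopper-Pearson limit 8.22%). It did not differ from the 2.81% of other protein-coding genes (Fisher's exact test, p = 0.634, not adjusted). By the nearest 5′ end at any distance, 2 of the 15 regulators were assigned a peak, pha-4 (3340 bp away) and eya-1 (2068 bp), which is 13.3% against 3.95% of other genes (adjusted p = 0.418, Fisher's exact test). In the top peaks of replicate 2 alone, pha-4 was bound, 1 of 15 (6.67% against 2.44%, adjusted p = 0.776, Fisher's exact test). The marker lists of body wall muscle (20 genes), intestine (20), epidermis (21) and neurons (28) also gave 0, and the germline and oocyte list gave 1 of 20, mex-1 (signal 204). By the nearest 5′ end, 3 epidermis genes were assigned a peak (ajm-1, dlg-1 and sqt-3; 14.3% against 3.95%, adjusted p = 0.201, Fisher's exact test), as were the body wall muscle genes unc-52 and unc-97, the intestine gene eps-8 and the neuron gene unc-104. The body wall muscle list also had 2 of 20 bound with the window of 2000 bp upstream (unc-52 and unc-97) and in the top peaks of replicate 1 alone (unc-52 and unc-60; adjusted p = 0.34, Fisher's exact test). In all, 1 of the 152 genes of these tissue lists was bound (0.658%, upper 95% Clopper-Pearson limit 3.61%). Neither this share nor any of the single lists differed from other genes (Fisher's exact test, p = 0.135 for the combined lists, adjusted p of 0.986 or higher for each list). Among regulator families, ceh-27 was the 1 bound gene of 63 homeobox genes named ceh (signal 185). Nuclear receptors had 6 of 269 (nhr-255, nhr-1, nhr-48, nhr-142, nhr-95 and nhr-59), with the nhr-255 summit within 200 bp of a tRNA gene. The 6 Hox, 25 bHLH, 19 T-box and 6 GATA genes had 0. At these list sizes the data cannot exclude an enrichment, even a strong one in the smallest lists. The limit for 0 bound members, by 3 counts over the number of members, was 20% for the 15 pharynx regulators and 13.6% for the 22 gland and cuticle genes. It was 50% for the 6 pharyngeal muscle genes, as for the Hox and the GATA genes.

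Below the optimal list, some of the named pharynx genes carried weaker summits. In the relaxed pooled list, pha-4 had a summit 253 bp upstream of its 5′ end with a signal of 110 and rank 1116 (rank 1563 in replicate 1 and 754 in replicate 2). At tbx-2 the summit ranked 1649 (signal 96.1; rank 1612 and 6104 in replicates 1 and 2), and at ceh-22, which PHA-2 is known to keep off in the isthmus muscles, it ranked 2339 (signal 85.5; ranks 3050 and 2947). The pharyngeal myosin gene myo-2 ranked 2544 (signal 83.2), but the replicates placed it at ranks 20939 and 1175. The relaxed list is deep, and 39.6% of all protein-coding genes had a relaxed pooled summit in their window. The pharynx regulators had 9 of 15 (adjusted p = 0.264), the pharyngeal muscle genes 2 of 6 (adjusted p = 1), the gland and cuticle genes 4 of 22 (18.2%, adjusted p = 0.181), the body wall muscle genes 13 of 20 (adjusted p = 0.181) and the ribosomal protein genes 66 of 77 (85.7%, adjusted p = 1.32e-15, Fisher's exact test over 15 lists).

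Neither the tagged gene nor the transformation marker stood out. No summit of any relaxed ce11 list lay in the promoter window of pha-2 (chromosome X, 633368 to 636993, minus strand) or of unc-119 (chromosome III, 10902641 to 10908935, plus strand), and the closest optimal summits were 43538 bp and 45613 bp from their 5′ ends. Within 20 kb of the pha-2 5′ end there were 0 optimal summits, against a mean of 0.334 around 10000 random gene starts (one-sided permutation p = 1), and within 50 kb there was 1 (p = 0.46).

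The DNA under the summits was GC-rich and poor in the homeodomain core. Over the 877 windows of 151 bp whose flanks fit in the chromosome, GC content was 45.9% ± 8.56 (SD across windows) at summits and 36.0% ± 8.15 in the paired flanks 500 bp away (sign-flip permutation p = 1e-05). The HEX-type core WATTAA was found in 17.8% of summit windows and 31.0% of flank windows (McNemar's exact test, adjusted p = 3.17e-10 over 13 motifs). In the same direction were the GATA site WGATAA (9.69% against 22.5%, exact adjusted p = 9.66e-13), the trans-splice acceptor TTTCAG (10.1% against 27.5%, adjusted p = 4.07e-20) and, with the smallest difference, TAATTA (4.56% against 7.41%, exact adjusted p = 0.029). The call for TAATTA did not hold, as it passed in none of the alternatives run (exact or permutation adjusted p from 0.0613 to 1). Its difference was −2.96 points with 150 bp around the summit and −3.42 in the 439 optimal peaks of highest signal. With 50 bp around the summit it was −1.37, and against shuffled windows it was 0. Higher at summits were the GA repeat GAGAGA (25.1% against 9.46%, exact adjusted p = 1.04e-16) and the GC box CCGCCC (10.9% against 3.08%, adjusted p = 1.88e-10). The fork head site TRTTKRY, the class bound by PHA-4, was at 39.8% against 36.7% (exact adjusted p = 0.315). It passed in the top peaks of replicate 1 alone (6.39 points higher at summits, exact adjusted p = 0.015), as did the E box CAGCTG (2.39 points, exact adjusted p = 0.016). In the top peaks of replicate 2 alone the differences were −0.228 points for the fork head site and −0.342 for CAGCTG, and in the 439 optimal peaks of highest signal −0.913 and 4.11 points, of which only CAGCTG passed (exact adjusted p = 0.00636). Without peaks within 200 bp of a tRNA or snoRNA gene, a setting chosen after the data were seen, the fork head site was 6.33 points higher at summits (exact adjusted p = 0.0464).

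Base composition accounted for part of these differences. Against 100 dinucleotide-shuffled copies of the same summit windows, WATTAA (shuffled median 20.1%), TAATTA (4.56%) and TTTCAG (10.4%) did not differ (adjusted permutation p of 0.225 or higher). The GA repeat (9.69%), the GC box (5.25%) and the GATA site (13.3%) kept their directions (adjusted permutation p = 0.0368 each, the smallest these shuffles can give). The fork head site then stood above its shuffled median of 28.4% (adjusted permutation p = 0.0368), as did CAGCTG (4.79% against 2.96%) and the CRE TGACGTCA (0.798% against 0.228%), and the T-box site GGTGTGA stood below (0.684% against 1.82%). In the main setting none of these sequences differed from its paired flanks (McNemar's exact test, adjusted p from 0.253 to 0.649). The CRE share over both flanks was also 0.798%. A difference from shuffled copies of summit windows alone does not show that a sequence is particular to summits. In the screen of all 2080 words of 6 bases, 833 passed the adjusted threshold, 481 higher and 352 lower at summits. The higher words held a mean of 4.18 G or C bases and the lower words 1.60. The screen compared summits with flanks only, so it does not separate a preference for a word from base composition. The highest-ranking words were CGCGCA (15.7% of summit windows against 2.39% of flanks), AGAGAG (21.2% against 5.36%) and GCGCGC (11.9% against 1.14%), and the lower ones were led by AAAAAT (36.3% against 59.5%).

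**Figure D4:**
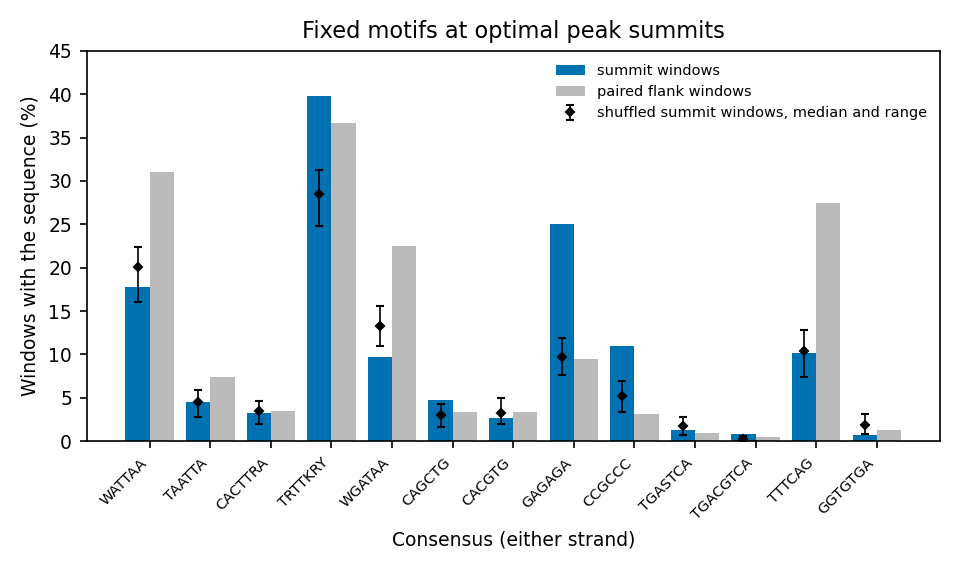
Share of summit windows (blue) and paired flank windows (grey) holding each of the 13 fixed sequences on either strand (y axis in % of 877 windows), with the median and range of 100 dinucleotide-shuffled copies of the summit windows (diamonds). GAGAGA and CCGCCC lie above both backgrounds, whereas WATTAA lies below its flanks and within its shuffled range.

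Chromosome X held more of the peaks than its genes would give. It carried 184 of the 878 optimal peaks (21.0%, 95% Wilson interval 18.4 to 23.8), against 12.8% of annotated gene 5′ ends (exact binomial test, two-sided, p = 1.96e-11) and 17.7% of the genome's length (p = 0.0117). Against protein-coding gene ends alone, the 856 nuclear peaks had 21.5% on X where 13.7% would be given (exact binomial p = 3.96e-10). Peaks near tRNA genes made up much of this: of the 151 nuclear peaks within 200 bp of a tRNA gene, 72 (47.7%) lay on X, which also holds 45.1% of the nuclear tRNA genes. The other 705 nuclear peaks had 15.9% on X (13.4 to 18.8, exact binomial p = 0.0893 against protein-coding gene ends). That interval lies above the 12.8% of all annotated gene 5′ ends, a baseline against which these peaks were not tested.

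The optimal list on the older assembly held most of the same peaks. Of the 878 ce11 optimal peaks, 863 (98.3%) had a ce10 counterpart on the same chromosome with the same width, the same summit offset and a signal equal within 0.01%, and the ce10 optimal list held 897 peaks.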

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

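The settings without mitochondrial or RNA gene peaks, with relaxed-summit genes as background, with protein-coding ends for X and with only summits outside promoter windows were chosen after the data were seen. Of 311 alternative values, 267 stayed on their side of the threshold or within their spread, 20 fell below the threshold, 10 passed it, 5 called results turned direction and 9 moved. Among differences, 18 changed sign, 16 of them in results past the threshold neither before nor after. The overlap of replicate lists (64.1%) was 60.1% with at least 50% reciprocal overlap, 54.9% for summits within 100 bp, 72.8% for the top 500 and 44.2% for the top 5000. The rank correlation of 0.629 was 0.308 on the q value column and 0.743 in the 439 peaks of highest signal; the cause was not tested. The number of lists past the threshold (5) was 3 in those 439 peaks, a smaller set, and 3 with only genes that have a relaxed pooled summit as background, which has fewer genes; translation factors and the large chemoreceptor and lectin families were the lists lost. The share of summits in non-coding exons became 12.3% with a 500 bp window, which leaves bases downstream of the 5′ end to the other classes, and the bound share of the chemoreceptor and lectin families was 0.217 points above, not below, that of circular shifts. Among summits outside promoter windows, 2 location classes passed, against 6 for all summits. The intergenic share (42.4%) was then above the shifts, while the intron share (48.3%) did not differ from them. The promoter share no longer lowers either class in that comparison. Without peaks within 200 bp of a tRNA or snoRNA gene, the tRNA difference was −1.29 points, which the removal sets by construction, and snRNA and snoRNA genes stayed 4.61 points above other genes. No paired analysis was possible because there is 1 group. The unknown depth limits how far missing peaks can be read as absence.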

Other observations

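The tests of nearby RNA genes, of gene biotypes and of sequence near them were chosen after the gene list results had been seen, as were those of X without tRNA peaks and of the mitochondrial chromosome. What would be seen was written before the result for unique against copied tRNA genes, ribosomal protein genes after peak removal, X and the mitochondrial chromosome. It was written afterwards for the HEX-type site and for unique tRNA genes against shifts. Nothing was written for the gene biotypes, tRNA isotypes, peak ranks or shifts of peaks near RNA genes. For the distance to mitochondrial tRNA genes, the condition that a difference exceed its bootstrap spread was added after the value was seen, as was the condition that removing peaks must take out most ribosomal protein peaks to decide anything.

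The share of RNA genes rose steeply with peak rank. Of the 100 strongest nuclear peaks of the pooled list, 34 lay within 200 bp of a tRNA gene and 30 within 200 bp of a snoRNA gene. Of the next 200 nuclear peaks 36.0% lay near either kind, of the 556 after those 12.9%, of the following 1144 it was 7.52%, and beyond rank 10000 it was 0.751%. Among all 856 nuclear optimal peaks, 17.6% lay near a tRNA gene, against a median of 0.234% in circular shifts, and 6.66% near a snoRNA gene, against 0.117% (permutation p = 0.002 for each, the smallest the 1000 shifts can give). The share near either kind was 23.8% in the 854 nuclear peaks among the strongest of replicate 1 and 24.0% in the 857 of replicate 2. Summits near tRNA genes lay at a median of 31 bp downstream of the 5′ end, and those near snoRNA genes at a median position of −37 bp, with 87.7% upstream of the 5′ end. No tRNA isotype passed the test of its share against the others: shares ran from 46.2% of 13 tRNA-Cys genes to 17.4% of 46 tRNA-Lys genes among isotypes with more than 1 gene (adjusted p = 1 for each, Fisher's exact test).

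By biotype, 75 of 346 snoRNA genes (21.7%; odds ratio 10.4, 8.01 to 13.5; adjusted p = 3.77e-44, Fisher's exact test over 11 biotypes of nuclear genes) and 12 of 129 snRNA genes (9.30%; adjusted p = 0.000416) were bound. Genes of the broad ncRNA biotype were also bound more often than other nuclear genes, 373 of 7764 (4.80% against 2.32%, odds ratio 2.13, exact adjusted p = 1.78e-29). Some of them share a peak with another RNA gene, as F55A11.13 does with the snoRNA gene F55A11.10 and C42D8.14 with the tRNA gene C42D8.t1. Several also lay at the peak of cel-mir-52. The test treats genes as independent, so it does not show binding at ncRNA genes apart from such neighbours. By the same exact test, pseudogenes (0.517%, adjusted p = 5.03e-14) and piRNA genes (0.475%, adjusted p = 4.28e-125), which are clustered, were bound less often than other nuclear genes. MicroRNA genes had 13 of 261 bound (4.98%, exact adjusted p = 0.0536), among them cel-mir-52, cel-mir-51 (signal 640), cel-mir-1 (151) and cel-mir-58a (136). Protein-coding genes, at 2.74%, did not differ from other nuclear genes (exact adjusted p = 0.975). Outside their own test, the 15363 piRNA genes are among the other nuclear genes and lower the share of that group. The result for protein-coding genes therefore does not show equal binding with the remaining biotypes.

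The first pattern weighed is the place of tRNA and snoRNA genes among the strongest peaks. Of the 143 tRNA genes without an identical copy, 15.4% had a summit within 200 bp, against at most 3.50% in circular shifts. An identical copy of the gene is therefore not needed for a summit nearby. Reads shared with near-identical genes, or a summit of a copied neighbour within 200 bp, were not tested, so shared reads are not excluded there. For the 469 copied genes shared reads also stay open, because their share was higher (28.1%) and the ratio of unique to copied was 0.547 (95% interval 0.363 to 0.824). The HEX-type core was in 13.9% of the 208 windows near tRNA or snoRNA genes (9.54 to 19.4), which equals the shuffled median and leaves most windows without the core. The other 648 nuclear windows showed no excess of it either (17.3% against a shuffled median of 20.4%). With no set of peaks in which the core stood out, the test cannot decide whether the factor recognises it at these summits. Enrichment that follows highly transcribed genes stays open: with all 208 of these peaks removed, ribosomal protein promoters had an odds ratio of 12.5 (7.32 to 21.4), but only 1 of their 19 peaks lay near a tRNA or snoRNA gene and no table measures transcription. Whether PHA-2 itself is brought to these genes was not tested, as no untagged or unrelated library was analysed here.

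The second pattern is the excess of peaks on chromosome X. The tRNA gene content of X is a candidate explanation: without the 151 peaks near tRNA genes the X share was 15.9%, against 13.7% of protein-coding gene ends (exact binomial p = 0.0893), and a summit lay within 200 bp of 26.1% of the 276 tRNA genes on X and of 24.4% of the 336 on autosomes. A smaller excess in the remaining peaks is not excluded, since the interval reaches 18.8%. Its lower end, 13.4%, lies above the 12.8% of all annotated gene 5′ ends that lie on X. By that baseline an excess remains, so how far tRNA genes account for it depends on the baseline chosen. No biological explanation was tested.

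The third pattern is the mitochondrial signal. The pooled relaxed peaks covered 61.3% of the mitochondrial chromosome, against 12.6% of the nuclear genome, which lies between the bounds set for and against a high copy number that the control did not remove; that source and localised enrichment cannot be told apart without the read coverage of the control. Mitochondrial summits were not closer to mitochondrial tRNA genes than shifted ones, with a median distance of 343 bp (bootstrap interval 175 to 592.5) against 295.8 bp in the shifts, which lies inside that interval, and the 22 summits are too few to exclude such a preference. No biological explanation was tested.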
